A study of Ephydatia muelleri with 12 samples.

How the data were processed

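Poly(A) RNA was sequenced from whole freshwater sponges of the species Ephydatia muelleri that carried algal endosymbionts. The sponges were hatched from gemmules, the resting buds of the animal, in Strekal's solution and grown under 12 hours of light and 12 hours of dark, with the medium refreshed every 48 hours. Sponges were collected at developmental stages 1, 2, 3 and 5, with 3 libraries per stage numbered 1, 5 and 10, which makes 12 libraries. Per the labels' protocols, RNA was extracted from flash-frozen cultured tissue with a Norgen animal tissue kit, and libraries were made with the TruSeq stranded mRNA kit after selection of polyadenylated RNA on oligo-dT beads. Growth in the dark, which the title of the series names, was not analysed here. The labels give stage numbers and no description of the stages.

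Per the submitters' processing notes, reads were trimmed with cutadapt, checked with FastQC, aligned with HISAT2 and quantified or assembled with StringTie. Their versions, the genome build, the annotation release and the settings for strand and for reads with several matches are not given in the sources used here. The deposited table holds 35320 gene models with scaffold, start, end and strand. Per the file headers it has 12 columns of raw counts and 12 columns of FPKM, fragments scaled by transcript length and library size, which the authors calculated and rounded to 2 decimals. Counts are whole numbers that sum to between 50066269 and 58305586 per library, and no entry lacks a gene model. The table gives each gene model an identifier as its only name, and 14820 gene models also have a description, 17677 have Gene Ontology (GO) terms and 4514 have a KEGG pathway. The descriptions are best matches to proteins of 249 plant and algal species, with Klebsormidium nitens (1335 descriptions) and Lactuca sativa (1068) the most frequent, so a description names the closest plant or algal protein and not the sponge gene itself. All counts are on sponge gene models, so RNA of the algae was not measured.

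Counts were tested with edgeR 4.0.16 in R 4.3.3 using the quasi-likelihood F test on the counts as deposited. Genes were kept by filterByExpr, which left 28380 genes (15521 of them without a description), libraries were scaled with TMM factors, and 1 model with the 4 stages and no block was fitted to all 12 libraries with 8 residual degrees of freedom. A gene was called at a Benjamini-Hochberg (BH) adjusted p under 0.05 within a comparison. All adjusted p-values for genes are from this edgeR test with BH adjustment unless another tool is named. The comparisons, fixed before the data were examined, were stage 2 against stage 1, stage 3 against stage 2, stage 5 against stage 3 and stage 5 against stage 1, with an F test for a difference between any stages. The design had named limma on log2(FPKM + 1) for a table of FPKM alone, with edgeR to take its place should counts be present, as they were. Alternatives worded for FPKM (pseudocounts, quantile normalization) were run with limma 3.58.1 on log2(FPKM + pseudocount), where a fold change understates the change of genes with low values. Levels are given as CPM, counts scaled to library size with TMM factors, mean ± SD over 3 libraries, and changes as log2 fold change ± SE. This SE was derived as the size of the log2 change divided by the square root of the quasi-likelihood F statistic. It is approximate, above all for genes with a stage near 0. Genes at 0 counts in all libraries of a stage are given as listed at 0 with no fold change. The reason is that in each stage between 36 and 61 genes had at least 300 counts in 1 library and 0 in another, so a 0 in this table is not a plain measure of depth. Medians of gene lists are given again with such genes at the change that 3 counts over the stage would give, where that moved the median.

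In addition, 18 gene lists were fixed at the same time by patterns matched to the descriptions: chloroplast-matched genes, flagellum and axoneme, biosilica, extracellular matrix, cell adhesion, actomyosin, cell cycle and DNA replication, stem cell, innate immunity, lysosome, oxidative stress, chaperones, nitrogen, sugar and water transport, lipid metabolism, Wnt, TGF-beta and Notch signalling, light and circadian genes, cytosolic ribosomal proteins, and oxidative phosphorylation. The biosilica list matched 0 genes. Because descriptions come from plant and algal proteins, some lists hold other genes than their names say, and their members are named with the results. Lists were compared with all other genes by camera with a preset correlation of 0.01 and BH adjustment over the lists, and again with an estimated correlation. The fry test, also set in advance, asks whether the members of a list change, without comparing them with other genes. Its p-values were BH adjusted over the lists too. Lists with fewer than 5 tested genes were described and not tested. GO terms (1753) and KEGG pathways (101) with 10 to 500 tested genes were tested with a one-sided hypergeometric test (Fisher's exact test) against the tested genes that carry a term (15587 for GO and 4219 for KEGG), with BH adjustment per comparison and direction. This test treats genes as independent draws. Genes of a term that move together make its p-values too small, so they rank terms and do not measure the spread between libraries.

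Genes named in the text were chosen by a rule set then as well. Per comparison the rule took the 6 largest rises and 6 largest falls on the log2(FPKM + 1) scale among called genes with an informative description, no overlap between the libraries of the stages compared and a mean of at least 5 FPKM in the higher stage. It added up to 2 called members of each list with the smallest adjusted p, the best of each direction where a list had both. Where other genes are named, this is said. Coordinates are those of the deposited table.

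Principal components and correlations between libraries were computed on log2(FPKM + 1), apart from a check of the order of the stages on log2 CPM. The alternatives set in advance were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-ratio size factors, quantile normalization, a replicate block, robust quasi-likelihood, a fit of only the 2 stages compared and leaving out each library in turn. Alternatives chosen after seeing the data were limma on log2(FPKM + 1), DESeq2 1.42.0, scaling by library size alone, removal of each library's trend with transcript length, and leaving out the 4 libraries numbered 10. Transcript length was derived from counts and FPKM and was known for 96.9% of tested genes. Libraries of a stage were compared pair by pair with a chi-square test of their counts, and every pair differed by more than sampling noise (chi-square per degree of freedom of 22.7 to 184). All 12 were used as separate libraries. Libraries prepared separately from 1 sample could differ in this way too, so the test does not show that they came from separate cultures or animals. The edgeR step was tested on simulated data for stage 3 against stage 2 with 28380 genes of which 200 were changed: 13% of 2-fold and 68% of 4-fold changes were called, and 3.57% of calls were false. The changed genes were drawn only from genes with enough counts, and the simulated libraries held no deviation shared by replicate number. These rates may therefore be too favourable for the tested genes as a whole. Data were read and plotted with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

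Nothing in the labels says that the libraries of a stage came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. PCR copies were not marked by molecular identifiers, so counting error alone understates the error of single values. Genes with near-identical copies, such as the tandem alpha-actinin-like genes and the aquaporin NIP1-1 pair, are reported as uncertain because reads shared between copies could be split between them. The same holds for the carbonic anhydrase clusters, which are not named in the results.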

Results

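Whole-sponge poly(A) RNA was measured in 12 libraries of Ephydatia muelleri with algal endosymbionts, 3 at each of developmental stages 1, 2, 3 and 5. All sponges were grown under a light and dark cycle. The libraries with replicate numbers 1, 5 and 10 held 53963818, 58305586 and 57298305 counts at stage 1. They held 53515518, 50127930 and 54435036 counts at stage 2 and 53828324, 50066269 and 55189920 counts at stage 3. At stage 5 they held 56322370, 54586936 and 54850291 counts. The series addresses how algae and sponge are integrated over development, and the comparisons made here are those between stages in the light.

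Stage 1 stood apart from all later stages. Its 100 most abundant genes took 48.3% ± 2.83 of counts (SD, n = 3), against 25.9% ± 1.09 at stage 2, 26.9% ± 0.51 at stage 3 and 23.7% ± 1.77 at stage 5. The number of genes above 1 FPKM was 12548 ± 789 at stage 1, 16933 ± 59.1 at stage 2, 16023 ± 496 at stage 3 and 17566 ± 204 at stage 5. A PLAC8 motif gene (Em0024g58a) held 2.02% ± 0.397 of stage 1 counts. Superoxide dismutase [Cu-Zn] 2 (Em0023g415a), an enzyme that removes superoxide, held 0.900% ± 0.115. At stage 2 the most abundant gene, named here for its abundance outside the rule for named genes, was Em0023g963a (2.75% ± 0.957), whose GO term is deoxyribonuclease activity. Outside the rule too, Em0020g282a (2.26% ± 0.118) came next and carries the term structural constituent of cytoskeleton. The first principal component of log2(FPKM + 1) held 79.0% of the variance and separated stage 1 from the rest, and the second held 9.46%. Pearson correlations across genes averaged 0.978 within stage 1, 0.751 between stages 1 and 2, 0.780 between stages 1 and 3, and 0.728 between stages 1 and 5. They averaged 0.975 between stages 2 and 3, 0.966 between stages 2 and 5, and 0.941 between stages 3 and 5.

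**Figure D1:**
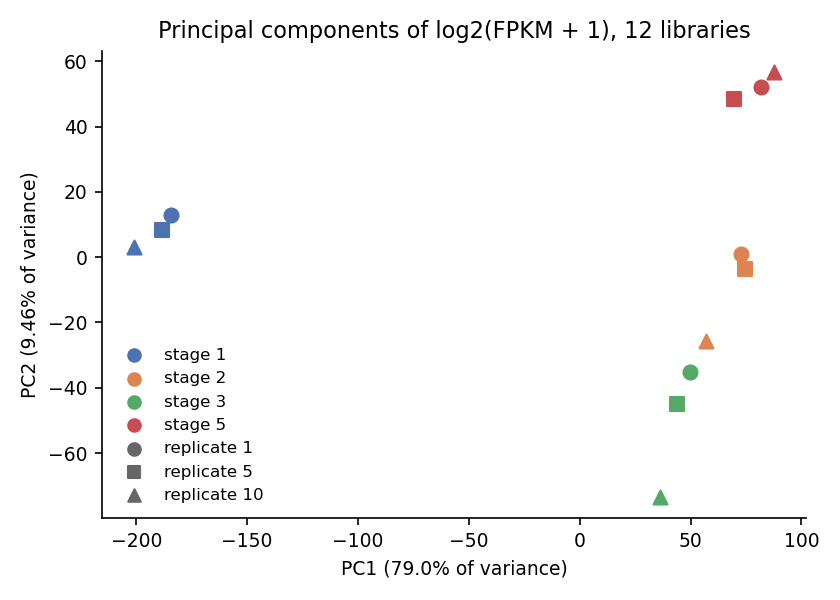
Scores of the 12 libraries on the first and second principal components of log2(FPKM + 1), with colour for the stage and marker shape for the replicate number. The first component (79.0% of the variance) separates the 3 stage 1 libraries from the 9 later ones.

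Between stage 1 and stage 2, 16 of 18 genes of the actomyosin list, 7 of 9 of the extracellular matrix list and 30 of 36 of the transport list were higher, and 43 of 44 cytosolic ribosomal protein genes were lower. With an estimated correlation the camera adjusted p was 0.165 for actomyosin, 0.0181 for extracellular matrix, 0.0262 for transport and 0.276 for ribosomal proteins. The fry adjusted p was 2.60e-06 for actomyosin, 4.65e-09 for extracellular matrix, 3.15e-09 for transport and 6.64e-05 for ribosomal proteins. Filamin (Em0006g636a, scaffold 6, 5948752 to 5979797, minus strand), which crosslinks actin filaments, rose from 1.21 ± 0.643 to 1422 ± 189 CPM (n = 3 per stage). Its log2 fold change was 10.18 ± 0.46 SE (edgeR adjusted p = 2.72e-08). A gene matching the transcription factor MCM1 (Em0144g2a, scaffold 144, 17443 to 19176, minus strand) rose 131-fold to 2617 ± 565 CPM (7.03 ± 0.26). The 60S ribosomal protein L31 gene (Em0022g699a, scaffold 22, 4627785 to 4630102, plus strand) fell from 5986 ± 1861 to 370.1 ± 48.2 CPM (-4.02 ± 0.32, adjusted p = 1.29e-06). Superoxide dismutase [Cu-Zn] 2 (Em0023g415a, scaffold 23, 2270164 to 2270916, minus strand) fell from 14780 ± 4643 to 557 ± 264 CPM (-4.73 ± 0.50). In all, edgeR called 16006 of 28380 tested genes, 9589 higher and 6417 lower at stage 2. Of these, 8125 and 5387 changed by at least 1 on the log2 scale.

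Other large rises covered several protein classes. A calcium-binding protein of the CML49 type (Em0005g1317a, scaffold 5, 11064901 to 11066277, plus strand) rose from 0.234 ± 0.216 to 327 ± 92.2 CPM. A ferulate-5-hydroxylase match with a heme binding term (Em0013g678a) rose from 2.80 ± 0.994 to 511 ± 88.5 CPM. Deoxyhypusine monooxygenase (Em0014g567a), which completes the hypusine residue of a translation factor, rose from 2.04 ± 1.20 to 344 ± 3.39 CPM. A match to plant cadmium resistance protein 2 (Em0001g1689a) and a pathogenesis-related PRB1-3-like gene (Em0007g283a) were listed at 0 in all stage 1 libraries. They reached 233 ± 54.2 and 186 ± 83.6 CPM at stage 2. Of the largest falls, a mannose-specific lectin (Em0002g1334a, scaffold 2, 13124573 to 13126396, plus strand) went from 627 ± 185 to 3.64 ± 2.33 CPM (-7.43 ± 1.38, adjusted p = 0.000736). Alpha-glucosidases, which release glucose from glycans and storage sugars, fell as well. Em0016g785a went from 1828 ± 717 to 31.8 ± 13.9 CPM and Em0023g785a from 1308 ± 607 to 19.1 ± 10.7 CPM. A match to plant cadmium resistance protein 7 (Em0024g59a, scaffold 24, 633226 to 633818, plus strand) fell from 6468 ± 3507 to 136 ± 71.8 CPM. A putative protease (Em0017g669a) fell from 310.5 ± 50.3 to 3.09 ± 2.56 CPM.

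In the actomyosin list, which here holds alpha-actinin-like and filamin genes, 16 of 18 members were higher and 2 were not called (16 higher adjusted over the list alone). The median log2 change was 4.20 (camera adjusted p = 1.15e-08, adjusted p = 0.165 with an estimated correlation). The alpha-actinin-like gene Em0011g498a rose from 6.67 ± 1.41 to 90.7 ± 9.72 CPM. Several alpha-actinin-like genes lie in tandem and could share reads, so their single values are uncertain. Of the extracellular matrix list, 7 of 9 genes were higher and 1 was lower (7 and 1 adjusted over the list alone). Its median was 3.84, and the camera call held (adjusted p = 2.69e-08, adjusted p = 0.0181 with an estimated correlation). Members of this list entered by words in the plant or algal match, so they need not be matrix proteins. The lower member, a collagen type IV alpha-3-binding protein match (Em0009g1200a), carries the GO term ceramide metabolic process. A subtilisin-related protease with thrombospondin repeats (Em0009g146a) rose from 2.03 ± 0.330 to 364 ± 60.4 CPM. In the transport list, 30 of 36 members were higher and 1 was lower (30 and 1 adjusted over the list alone). Near-identical copies can share reads, so the higher members need not be separate changes. The transport median was 4.15 with 13 members listed at 0 in some stage, and the camera call held (adjusted p = 1.53e-10, adjusted p = 0.0262 with an estimated correlation). Aquaporin-3-like (Em0014g565a, scaffold 14, 4716861 to 4721781, plus strand), a water and glycerol channel, rose from 18.2 ± 0.257 to 211 ± 15.2 CPM (3.53 ± 0.11, adjusted p = 2.98e-09). The member that fell, folylpolyglutamate synthase (Em0016g224a), makes folate polyglutamates and entered the list by its name. It went from 75.1 ± 7.82 to 36.7 ± 3.61 CPM and from 11.9 to 11.7 FPKM. The call ended with a pseudocount of 0.1 (-0.0264, adjusted p = 0.868), limma (-0.0244, 0.865) and library sizes alone (-0.12, 0.453). The aquaporin NIP1-1 genes Em0019g922a and Em0246g9a lie outside the rule for named genes and were chosen after their values were seen. They had fitted changes of 12.73 and 12.71 and are uncertain, since near-identical copies can share reads.

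The flagellum and axoneme list had 27 higher and 4 lower of 36 (28 and 4 adjusted over the list alone). Its median was 2.29 (camera adjusted p = 0.00227, adjusted p = 0.332 with an estimated correlation). The call also ended with a pseudocount of 0.1 (0.154), limma (0.188) and quantile normalization (median 0.90, adjusted p = 0.0554). A flagellar associated protein (Em0019g1180a) rose from 1.24 ± 0.218 to 11.5 ± 2.22 CPM. The outer dynein arm light chain 8 match Em0015g4a fell by 2.18 on the log2 scale to 33.9 ± 2.42 CPM. The innate immunity list holds mostly scavenger receptor genes that match deleted in malignant brain tumors 1. Of its 17 tested genes 11 were higher and 1 was lower (11 and 1 adjusted over the list alone), with a median of 2.51. The camera adjusted p was 0.0133, and the adjusted p was 0.0929 with an estimated correlation, 0.104 with a pseudocount of 0.1, 0.141 with limma and 0.0629 with library sizes alone. Scavenger receptor gene Em0128g4a rose from 4.95 ± 1.17 to 34.0 ± 5.13 CPM. Of 44 cytosolic ribosomal protein genes 43 were lower (43 adjusted over the list alone), with a median of -2.31, or -1.37 with library sizes alone. For these genes the camera adjusted p was 7.42e-21, and the adjusted p was 0.276 with an estimated correlation. The chaperone list had 13 higher and 30 lower of 63 (14 and 31 adjusted over the list alone). Its median was -0.49, but 0.43 with library sizes alone (camera adjusted p = 0.0133, adjusted p = 0.165 with an estimated correlation). The call ended with library sizes alone (adjusted p = 0.364), a pseudocount of 0.1 (0.177), limma (0.278) and quantile normalization (0.431). A 70 kDa heat shock protein gene (Em0024g143a) rose from 10.8 ± 0.273 to 58.5 ± 6.80 CPM. A DnaJ domain gene (Em0012g1092a) fell from 415 ± 30.6 to 122 ± 8.53 CPM.

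Camera called none of the other lists in this comparison (adjusted p from 0.193 to 0.907). The fry test called every tested list apart from adhesion (adjusted p = 0.0899) and light and circadian genes (0.187). The cell cycle list had 23 higher and 7 lower of 50 (23 and 7 adjusted over the list alone). Mcm2 (Em0001g1567a), part of the replicative helicase, rose from 24.2 ± 1.66 to 114 ± 8.48 CPM. A cyclin A match (Em0009g248a) fell from 87.7 ± 11.7 to 1.10 ± 0.763 CPM. Chloroplast-matched sponge genes had 46 higher and 30 lower of 111 (48 and 30 adjusted over the list alone). The OBGC1 GTP-binding protein match Em0004g354a fell from 1170 ± 291 to 142 ± 29.97 CPM. A chloroplast name in the plant match does not say where the sponge protein acts. The lysosome list had 15 higher and 7 lower of 33 (17 and 9 adjusted over the list alone). Niemann-Pick C1-like Em0005g706a, a cholesterol transporter, fell from 418 ± 95.0 to 107 ± 5.67 CPM. In the oxidative stress list 8 rose and 5 fell of 21 (8 and 5 adjusted over the list alone). Catalase (Em0014g600a), which breaks down hydrogen peroxide, rose from 40.7 ± 4.43 to 196 ± 3.41 CPM.

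Counts were 12 higher and 5 lower of 22 for oxidative phosphorylation, 9 and 1 of 26 for lipid metabolism, and 5 and 2 of 12 for cell adhesion (the same adjusted over the list alone). The adhesion members are mostly integrin-linked kinase matches. The Wnt, TGF-beta and Notch list holds notchless, strawberry notch and similar genes, and 3 of 5 were lower (3 adjusted over the list alone). Notchless (Em0015g1072a), known from ribosome assembly, fell from 112 ± 17.2 to 37.4 ± 7.94 CPM. Of 9 light and circadian genes 1 was higher and 2 were lower (1 and 1 adjusted over the list alone). Of 4 stem cell genes 2 were higher (2 adjusted over the list alone), and the Musashi-like gene Em0002g1885a rose from 311 ± 16.97 to 628 ± 25.4 CPM. The oxidative stress list had a median of -0.10 and a mean of 0.79. Lysosome and adhesion lists had medians of 0.40 and 0.35 with a camera direction below other genes. With library sizes alone the medians of the oxidative stress and of the light and circadian lists turned from -0.10 to 0.78 and from -0.24 to 0.71. The median of the Wnt, TGF-beta and Notch list went from -0.90 to 0.00283.

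GO and KEGG terms were tested on the same calls. Among higher genes 275 GO terms and 21 KEGG pathways were enriched. They included extracellular space (219 of 350 genes, adjusted p = 6.01e-20), calcium ion binding (187 of 302, 1.77e-16) and homophilic cell adhesion via plasma membrane adhesion molecules (44 of 52, 5.06e-10). Also enriched were axoneme (47 of 58, 1.65e-09), scavenger receptor activity (87 of 132, 2.05e-09) and the KEGG pathway Nitrogen metabolism (17 of 22, 0.00112). Among lower genes 83 GO terms and 6 KEGG pathways were enriched, with KEGG Ribosome (85 of 111, 3.57e-30), autophagosome (26 of 41, 5.14e-06) and ubiquitin protein ligase activity (84 of 215, 5.14e-06) among them. The share of higher genes among calls was 59.9% with TMM and 80.6% with library sizes alone. It was 84.0% with limma on log2(FPKM + 1), 84.2% with a pseudocount of 0.1 and 48.7% with quantile normalization. The median change of all genes was 0.20 with TMM and 1.08 with library sizes alone, so directions of small changes hold relative to the TMM scale.

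**Figure D2:**
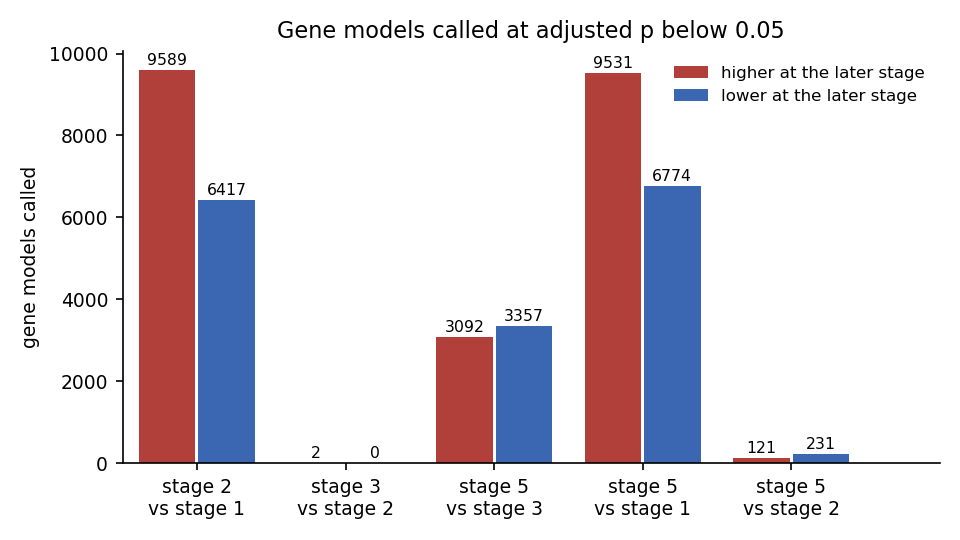
Number of genes called higher and lower (edgeR, adjusted p under 0.05) in each comparison of stages. Stage 2 against stage 1 gave 9589 higher and 6417 lower genes, stage 3 against stage 2 gave 2 and 0, and stage 5 against stage 3 gave 3092 and 3357 (1825 and 1572 without stage 3 replicate 10, 1867 and 1951 without stage 5 replicate 1).

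**Figure D3:**
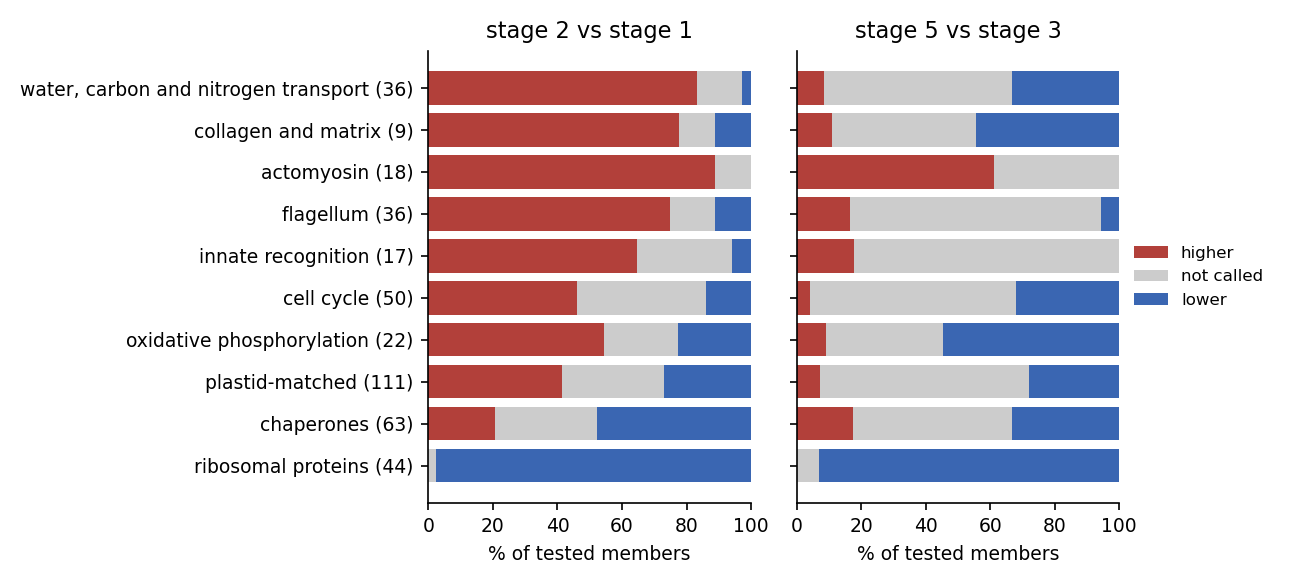
Percent of the tested members of 10 gene lists called higher, lower or not called for stage 2 against stage 1 and for stage 5 against stage 3. Of 44 cytosolic ribosomal protein genes 43 were lower at stage 2 than at stage 1 and 41 were lower at stage 5 than at stage 3.

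Between stage 2 and stage 3 only 2 genes passed the edgeR test, both higher at stage 3. Both lie outside the rule for named genes and were chosen after their values were seen. Em0127g7a (scaffold 127, 50218 to 51166, minus strand), with the GO terms lipid metabolic process and phosphoric diester hydrolase activity, rose from 14.4 ± 2.22 to 76.9 ± 21.2 CPM (2.42 ± 0.27, adjusted p = 0.0345, n = 3 per stage). Em0071g7a (scaffold 71, 48526 to 49996, plus strand), which has no description, was listed at 0 in all stage 2 libraries. It stood at 3.41 ± 1.10 CPM at stage 3 and 28.8 ± 1.63 CPM at stage 1 (adjusted p = 0.0345). At an unadjusted p under 0.05 edgeR gave 3279 of 28380 genes, a larger share than the 0.05 expected with no change. In the simulation 13% of 2-fold changes were called, so the few calls do not show that the stages are alike. DESeq2 called 682 genes (154 higher and 528 lower) and limma on log2(FPKM + 1) called 467 (16 and 451). A pseudocount of 0.1 gave 184 (10 and 174) and quantile normalization 145 (16 and 129). Without stage 3 replicate 1 edgeR called 94 genes, 5 higher and 89 lower. Without replicate 1 or 5 of stage 1, replicate 1 or 5 of stage 2, stage 3 replicate 10 or stage 5 replicate 1 it called 0. Leaving out stage 2 replicate 10, stage 3 replicate 5 or replicate 5 or 10 of stage 5 gave 1 gene.

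No gene of any fixed list was called over all genes tested between stages 2 and 3. The fry test called no list (adjusted p from 0.121 to 0.939). Adjusted over the list alone, 9 of 18 actomyosin genes were lower, with a list median of -0.93 (camera adjusted p = 1.22e-07, adjusted p = 0.327 with an estimated correlation). Likewise lower were 1 innate immunity gene, 1 oxidative stress gene and 2 oxidative phosphorylation genes, and 0 in every other list. The 44 cytosolic ribosomal protein genes had a median of 0.53 (camera adjusted p = 6.34e-16, adjusted p = 0.438 with an estimated correlation). Camera with the preset correlation also called chloroplast-matched genes (median 0.17, adjusted p = 0.00276), cell cycle genes (0.13, 0.00403) and chaperones (0.14, 0.0098). With an estimated correlation the adjusted p was 0.438 for chloroplast-matched genes and 0.327 for cell cycle and chaperones. Camera called oxidative phosphorylation (0.26, 0.0244) and flagellum and axoneme genes (-0.31, 0.0244) too, each with an adjusted p of 0.438 with an estimated correlation. With library sizes alone the medians were 0.0301 for chloroplast-matched genes, -0.0302 for cell cycle genes, 0 for chaperones and 0.12 for oxidative phosphorylation. They were then -0.45 for flagellum, -1.05 for actomyosin and 0.38 for ribosomal proteins. Changes from stage 2 to stage 3 correlated with transcript length across genes, which are not independent replicates (rank correlation -0.226). With each library's length trend removed the median was -0.65 for actomyosin and 0.44 for ribosomal proteins. Calls ended with quantile normalization for chloroplast-matched, cell cycle and flagellum genes (each 0.0678) and for chaperones and oxidative phosphorylation (each 0.823). With limma they ended for chloroplast-matched (0.0507), cell cycle (0.0606), flagellum (0.0547), chaperones (0.261) and oxidative phosphorylation (0.167). With a pseudocount of 0.1 they ended for flagellum (0.0625), chaperones (0.246) and oxidative phosphorylation (0.244), and with library sizes alone for chaperones (0.0923) and oxidative phosphorylation (0.201). The oxidative phosphorylation call also ended with the length trend removed (0.160) and without the libraries numbered 10 (0.525). The flagellum and axoneme call ended without stage 2 replicate 1 (adjusted p = 0.0657), stage 2 replicate 5 (0.130) or stage 3 replicate 10 (0.0998), and the chaperone call without stage 3 replicate 10 (0.0645). The oxidative phosphorylation call ended without stage 2 replicate 10 (0.247), stage 3 replicate 1 (0.0653) or stage 3 replicate 10 (0.243).

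The remaining lists were not called between stages 2 and 3, but transport was without stage 3 replicate 5 (adjusted p = 0.0406) and light and circadian genes without stage 2 replicate 10 (0.0445). Their medians were -0.20 for innate immunity, 0.28 for light and circadian genes, 0.34 for stem cell genes (not tested) and 0.16 for Wnt, TGF-beta and Notch. They were 0.12 for adhesion, 0.11 for oxidative stress, 0.08 for lysosome, 0.07 each for transport and extracellular matrix, and 0.02 for lipid metabolism. Of these medians 6 lay below 0 with library sizes alone: adhesion -0.00912, oxidative stress -0.0380, lysosome -0.0619, transport -0.0629, extracellular matrix -0.0631 and lipid metabolism -0.13. Means were below 0 for adhesion (-0.11), oxidative stress (-0.29), lipid metabolism (-0.15) and light and circadian genes (-0.89), against medians above 0. No GO term or KEGG pathway was enriched.

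Between stage 3 and stage 5, 41 of 44 cytosolic ribosomal protein genes were lower, and 11 of 18 genes of the actomyosin list and 31 of 52 of the GO term homophilic cell adhesion via plasma membrane adhesion molecules were higher. With an estimated correlation the camera adjusted p was 0.280 for ribosomal proteins and 0.272 for actomyosin. The fry adjusted p was 0.0111 for ribosomal proteins and 0.0037 for actomyosin. Of the fixed adhesion list, which holds mostly integrin-linked kinase matches and was defined apart from that GO term, 0 of 12 were called. Of 44 cytosolic ribosomal protein genes 41 were lower and 3 were not called (42 lower adjusted over the list alone). Their median log2 change was -0.94, or -0.68 with library sizes alone (camera adjusted p = 5.58e-15, adjusted p = 0.280 with an estimated correlation). The 60S ribosomal protein L28-1-like gene (Em0162g4a) fell from 441 ± 101 to 174 ± 75.5 CPM (-1.34 ± 0.31, edgeR adjusted p = 0.0116, n = 3 per stage). The 40S ribosomal protein S30 gene (Em0018g1157a) fell from 617 ± 99.4 to 320.1 ± 85.9 CPM (-0.95 ± 0.22, adjusted p = 0.0122). Both calls ended without stage 3 replicate 10 (adjusted p = 0.0577 and 0.0647). In the actomyosin list 11 of 18 genes were higher and 0 lower (12 and 0 adjusted over the list alone), with a median of 1.63. The camera adjusted p was 3.26e-06, and the adjusted p was 0.272 with an estimated correlation. Alpha-actinin-like Em0010g739a rose from 11.1 ± 3.56 to 43.3 ± 14.3 CPM and its neighbour Em0010g737a from 40.6 ± 9.95 to 133 ± 15.8 CPM, both uncertain as tandem copies. In all 6449 genes were called, 3092 higher and 3357 lower at stage 5, with 2438 and 1333 changed by at least 1 on the log2 scale. Without stage 3 replicate 10 there were 1825 higher and 1572 lower, of which 1547 and 612 changed by at least 1. Without stage 5 replicate 1 there were 1867 and 1951, with 1623 higher by at least 1. Leaving out stage 3 replicate 5 gave 1941 higher genes, and leaving out stage 5 replicate 10 gave 2209 lower genes, 847 of them by at least 1.

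Among the genes taken by the rule for large rises was a match to the translocase subunit SecA (Em0001g600a, scaffold 1, 4993923 to 4995860, plus strand), from 2.80 ± 3.49 to 57.2 ± 21.7 CPM (4.35 ± 0.94, adjusted p = 0.0124). A neurotrypsin match (Em0010g816a, scaffold 10, 8158687 to 8172331, plus strand), a secreted serine protease with scavenger receptor domains in animals, rose from 5.86 ± 5.93 to 92.6 ± 12.8 CPM (3.98 ± 0.70, 0.00384). The alpha-glucosidases that fell by stage 2 were higher at stage 5 than at stage 3. Em0016g785a went from 26.5 ± 22.1 to 186 ± 110 CPM (2.81 ± 0.89, 0.0423) and Em0023g785a from 15.1 ± 13.0 to 145 ± 85.3 CPM (3.27 ± 1.04, 0.0435). Both calls ended when any of 10 single libraries was left out, with adjusted p up to 0.121 and 0.111 (both without stage 5 replicate 5).

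Among the falls, purple acid phosphatase 17 (Em0018g127a, scaffold 18, 697267 to 701826, minus strand), an iron-containing phosphatase, went from 186 ± 42.0 to 36.9 ± 3.66 CPM (-2.33 ± 0.19, adjusted p = 0.000716). A rab-type small GTPase gene (Em0018g708a), of a family that directs vesicle traffic, fell from 105 ± 22.7 to 22.2 ± 6.20 CPM (-2.25 ± 0.38, 0.0033). The cadmium resistance 7-like gene Em0024g59a fell again, from 351 ± 151 to 65.8 ± 43.4 CPM (-2.42 ± 0.58, 0.0141). That call ended without stage 3 replicate 10 (adjusted p = 0.0607) and without stage 5 replicate 1 (adjusted p = 0.0582).

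In the transport list 3 genes were higher and 12 lower of 36 (3 and 13 adjusted over the list alone). Its median was -0.29 (camera adjusted p = 0.0158, adjusted p = 0.272 with an estimated correlation). The call ended with a pseudocount of 0.1 (median -0.0875, adjusted p = 0.222), limma (0.0326, 0.311) and library sizes alone (-0.0321, 0.0538). It ended with quantile normalization (-0.29, 0.574) and without the libraries numbered 10 (-0.23, 0.109) as well. An ammonium transporter (Em0019g776a) rose from 6.60 ± 1.88 to 22.7 ± 1.46 CPM. Glutamine synthetase-like (Em0002g46a), which binds ammonium into glutamine, fell from 341 ± 37.6 to 134 ± 2.80 CPM. Oxidative phosphorylation had 2 higher and 12 lower of 22 (2 and 17 adjusted over the list alone). Its median was -0.63 (camera adjusted p = 0.00194, adjusted p = 0.280 with an estimated correlation), and the call ended with quantile normalization (-0.21, adjusted p = 0.648). Its median was -0.37 with library sizes alone. A mitochondrial ATP synthase subunit 6 match (Em0016g908a) rose from 0.818 ± 0.386 to 14.1 ± 4.22 CPM. Chloroplast-matched genes had 8 higher and 31 lower of 111 (8 and 35 adjusted over the list alone). Their median was -0.28 (camera adjusted p = 0.00194, adjusted p = 0.280 with an estimated correlation), or -0.00873 with library sizes alone. D-3-phosphoglycerate dehydrogenase 1 (Em0004g340a), of serine synthesis, fell from 509 ± 110 to 139 ± 8.65 CPM.

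Cell cycle genes had 2 higher and 16 lower of 50 (2 and 17 adjusted over the list alone). The median was -0.34 (camera adjusted p = 0.00401, adjusted p = 0.272 with an estimated correlation), or -0.0797 with library sizes alone. The call ended with a pseudocount of 0.1 (median -0.10, adjusted p = 0.0871), limma (-0.0914, 0.0762) and quantile normalization (-0.34, 0.0501). Proliferating cell nuclear antigen (Em0017g944a, scaffold 17, 8212325 to 8217430, minus strand), the sliding clamp of DNA replication, fell from 242 ± 54.6 to 116 ± 15.9 CPM (-1.07 ± 0.17). Flagellum and axoneme genes had 6 higher and 2 lower of 36 (9 and 3 adjusted over the list alone), with a median of 0.61. The camera adjusted p was 0.0225, or 0.0514 without stage 5 replicate 10, and the adjusted p was 0.325 with an estimated correlation. Intraflagellar transport protein 172 (Em0022g326a), of the transport system that builds flagella, rose from 17.5 ± 5.12 to 41.5 ± 12.8 CPM.

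None of the other lists was called by camera between stages 3 and 5 (adjusted p from 0.0891 to 0.627). The fry test did not call adhesion (adjusted p = 0.237), lysosome (0.454) or oxidative stress (0.111). Nor did it call lipid metabolism (0.158) or light and circadian genes (0.162). It called every other tested list. Chaperones had 11 higher and 21 lower of 63 (17 and 22 adjusted over the list alone). Heat shock cognate 70 (Em0014g963a) rose from 3.19 ± 0.240 to 8.84 ± 2.56 CPM. T-complex protein 1 theta (Em0023g499a), a subunit of the folding chamber for actin and tubulin, fell from 426 ± 11.1 to 257 ± 9.45 CPM, a call that ended with quantile normalization (adjusted p = 0.0759). In the innate immunity list 3 of 17 were higher (3 adjusted over the list alone). Scavenger receptor genes Em0004g1602a and Em0128g4a rose from 1.25 ± 0.505 to 8.40 ± 0.529 CPM and from 26.9 ± 0.637 to 53.7 ± 3.06 CPM. The extracellular matrix list had 1 higher and 4 lower of 9 (2 and 5 adjusted over the list alone). This list was called without stage 5 replicate 10 (camera adjusted p = 0.0246). It was also called with the length trend removed (0.0127) and without the libraries numbered 10 (0.0144). Prolyl 4-hydroxylase 3 (Em0002g41a), of an enzyme family that modifies collagen in animals, fell from 373 ± 104 to 108 ± 14.6 CPM. Of 4 stem cell genes 3 were lower (3 adjusted over the list alone), with pumilio 4-like (Em0005g1324a), of a family of RNA-binding repressors, down from 10.1 ± 2.61 to 1.87 ± 0.776 CPM.

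Lipid metabolism had 2 higher and 6 lower of 26 (2 and 6 adjusted over the list alone) and oxidative stress 1 and 3 of 21 (1 and 6 adjusted over the list alone). Camera called oxidative stress without stage 3 replicate 5 (adjusted p = 0.0386). For lysosome 1 and 2 of 33 were called (1 and 2 adjusted over the list alone), and for Wnt, TGF-beta and Notch 0 and 2 of 5 (0 and 3 adjusted over the list alone). Light and circadian genes had 0 and 1 of 9 (0 and 1 adjusted over the list alone) and adhesion 0 and 0 of 12 (0 and 0 adjusted over the list alone). Medians and means differed in sign for chaperones (-0.13 and 0.23), oxidative stress (-0.32 and 0.03), lysosome (-0.02 and 0.07), lipid metabolism (-0.0625 and 0.00404), and light and circadian genes (-0.19 and 1.00). With library sizes alone the medians of chaperones (0.14), lysosome (0.24), lipid (0.19), adhesion (0.13) and light and circadian genes (0.0705) lay above 0. Those of extracellular matrix (-0.0216) and oxidative stress (-0.0582) then lay near 0.

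Of GO and KEGG terms, 229 and 8 were enriched among genes higher at stage 5. They were led by homophilic cell adhesion via plasma membrane adhesion molecules (31 of 52, adjusted p = 1.10e-13) and included hippo signaling (20 of 27, 1.26e-11). Also enriched among these were scavenger receptor activity (43 of 132, 7.23e-09) and G-protein coupled receptor signaling pathway (49 of 173, 7.46e-08). Among lower genes 104 GO terms and 13 pathways were enriched. These included structural constituent of ribosome (106 of 153, 6.52e-47), protein folding (45 of 78, 7.52e-15) and proteasome complex (17 of 22, 2.18e-08). For the cytosolic ribosomal protein list camera estimated a correlation between genes of 0.889, for which the term test makes no allowance. All genes of the chaperonin-containing T-complex were lower (12 of 12, 2.10e-08), and Aminoacyl-tRNA biosynthesis was enriched (40 of 80, 4.27e-06). The count of 6449 called genes fell to 3397 without stage 3 replicate 10 and to 3818 without stage 5 replicate 1. The share of higher genes was 47.9% with TMM, 73.2% with library sizes alone, 67.7% with limma and 67.3% with a pseudocount of 0.1. Changes from stage 3 to stage 5 also correlated with transcript length across genes, which are not independent replicates (rank correlation 0.217). With each library's length trend removed the ribosome term had a median of -0.65 in place of -0.89, and 85 in place of 106 genes lower. The adhesion term then had a median of 0.87 in place of 1.52. In that setting 137 in place of 229 GO terms were enriched among higher genes.

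**Figure D4:**
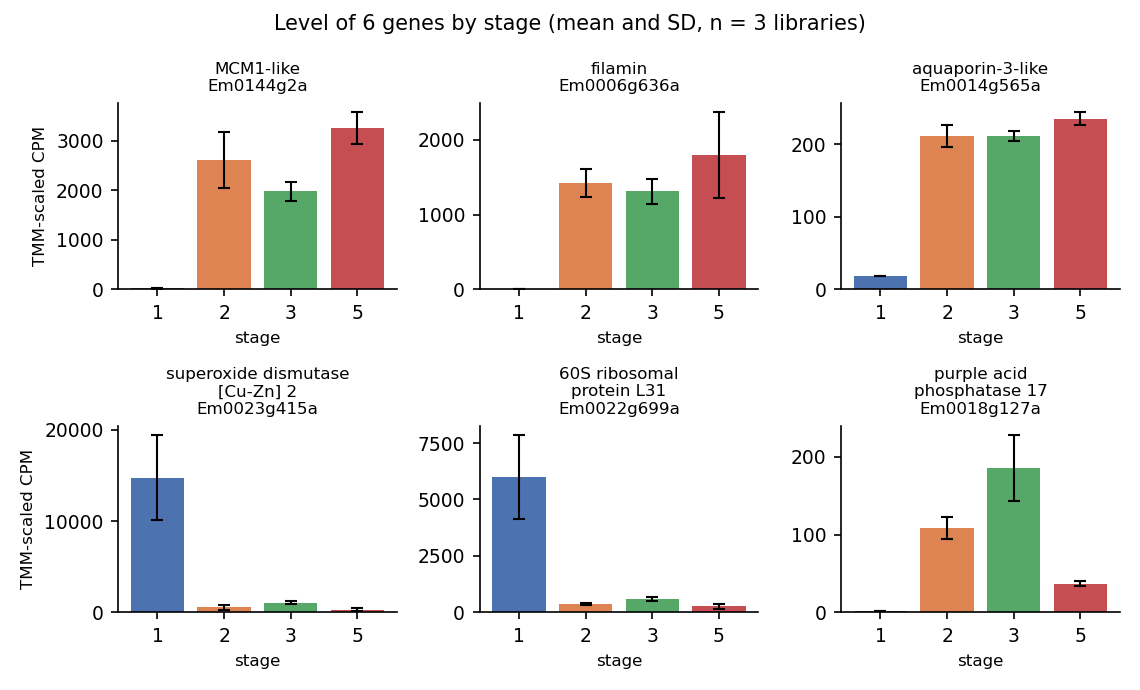
Mean and SD (n = 3) of TMM-scaled CPM at stages 1, 2, 3 and 5 for 6 named genes, each on its own axis. Filamin went from 1.21 CPM at stage 1 to 1422 CPM at stage 2, and the ribosomal protein L31 gene from 5986 to 370.1 CPM.

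Across the whole course, from stage 1 to stage 5, genes with the GO terms extracellular space (221 of 350, adjusted p = 4.18e-23), scavenger receptor activity (95 of 132, 6.40e-15) and actin binding (87 of 138, 4.82e-09) were enriched among higher genes. The PLAC8 motif gene Em0024g58a (scaffold 24, 626086 to 631911, plus strand) fell from 33458 ± 12845 to 406 ± 248 CPM (-6.37 ± 0.59, edgeR adjusted p = 3.59e-06, n = 3 per stage). The neighbouring Em0024g59a fell from 6468 ± 3507 to 65.8 ± 43.4 CPM, and serine decarboxylase 2 (Em0013g963a) from 2606 ± 327 to 46.3 ± 24.4 CPM. Villin-3-like (Em0007g932a), which binds and bundles actin, rose from 0.0711 ± 0.123 to 312 ± 17.4 CPM (11.99 ± 0.63, 6.42e-08). A pathogenesis-related protein 1 match (Em0007g1534a) rose from 0.0904 ± 0.157 to 188 ± 34.0 CPM. Filamin reached 1792 ± 576 CPM. A gene matching deleted in malignant brain tumors 1 (Em0011g283a), a scavenger receptor protein, rose from 0.0977 ± 0.169 to 40.5 ± 8.96 CPM. The mitochondrial ATP synthase beta subunit (Em0004g1559a) rose from 275 ± 29.3 to 1318 ± 63.7 CPM. In total 16305 genes were called, 9531 higher and 6774 lower, with 8271 and 5586 changed by at least 1 on the log2 scale.

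Of the lists, extracellular matrix had 8 higher and 1 lower of 9 (8 and 1 adjusted over the list alone) and a median of 3.96. Its camera call held with an estimated correlation (adjusted p = 2.87e-07, adjusted p = 0.0187 with an estimated correlation). The lower member, Em0009g1200a, was called higher with a pseudocount of 0.1 (0.43, limma adjusted p = 0.0293) and limma on log2(FPKM + 1) (0.42, 0.0274). Actomyosin had 16 of 18 higher (16 adjusted over the list alone) and a median of 4.97 (camera adjusted p = 1.62e-09, adjusted p = 0.164 with an estimated correlation). Transport had 28 higher and 1 lower of 36 (28 and 1 adjusted over the list alone). The transport median was 4.95, or 3.87 with members listed at 0 set to the change that 3 counts allow (camera adjusted p = 9.90e-09, adjusted p = 0.0516 with an estimated correlation). Flagellum and axoneme had 29 higher and 3 lower of 36 (29 and 5 adjusted over the list alone) and a median of 2.40 (camera adjusted p = 0.000716, adjusted p = 0.246 with an estimated correlation). That call ended with a pseudocount of 0.1 (0.0989) and limma (0.105). Innate immunity had 13 of 17 higher (13 adjusted over the list alone) and a median of 3.44, or 3.19 with members at 0 set likewise (camera adjusted p = 0.00458, adjusted p = 0.0516 with an estimated correlation). It was not called with a pseudocount of 0.1 (0.0616) or limma (0.0626). Ribosomal protein genes were lower in 43 of 44 (43 adjusted over the list alone). Their median was -2.73, or -1.67 with library sizes alone (camera adjusted p = 9.22e-25, adjusted p = 0.182 with an estimated correlation). Chaperones had 12 higher and 33 lower of 63 (12 and 34 adjusted over the list alone). The chaperone median was -0.84, but 0.18 with library sizes alone (camera adjusted p = 0.0109, adjusted p = 0.164 with an estimated correlation). The chaperone call ended with library sizes alone (adjusted p = 0.514), a pseudocount of 0.1 (0.193), limma (0.266) and quantile normalization (0.281).

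The other lists were not called by camera from stage 1 to stage 5. The fry test did not call adhesion (adjusted p = 0.518), oxidative phosphorylation (0.583) or light and circadian genes (0.192). It called every other tested list. There were 42 higher and 33 lower of 111 chloroplast-matched genes, 22 and 7 of 50 cell cycle, 14 and 9 of 33 lysosome, and 8 and 6 of 21 oxidative stress genes. Counts were 11 and 3 of 26 for lipid, 8 and 6 of 22 for oxidative phosphorylation, and 4 and 3 of 12 for adhesion. They were 0 and 3 of 5 for Wnt, TGF-beta and Notch, 1 and 1 of 9 for light and circadian, and 2 and 0 of 4 for stem cell genes. Adjusted over the list alone they were the same except for oxidative stress (8 and 7), lipid (10 and 3) and light and circadian genes (0 and 1). Medians and means differed in sign for oxidative stress (-0.11 and 0.54). With library sizes alone the medians were 0.89 for oxidative stress and 0.63 for light and circadian genes (-0.37 with TMM). Camera placed chloroplast-matched, lysosome, adhesion and oxidative phosphorylation genes below other genes although their medians were 0.07, 0.32, 0.29 and 0.21. The share of higher calls was 58.5% with TMM, 82.6% with library sizes alone, 84.4% with limma, 84.9% with a pseudocount of 0.1 and 47.0% with quantile normalization.

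In total 17184 genes differed between any stages by the edgeR F test. The most frequent courses were a rise from stage 1 to 2 with no later call (5687 genes, 33.1%; 2319 with quantile normalization) and a fall from stage 1 to 2 with no later call (4593, 26.7%, and 1294 with limma). Filamin was of the first kind (adjusted p = 0.329 from stage 3 to 5), while the MCM1-like gene Em0144g2a, chosen for this comparison after its values were seen, also rose from stage 3 to 5, from 1978 ± 193 to 3256 ± 318 CPM (0.72 ± 0.20, adjusted p = 0.0242). In all 1933 genes rose at both the first and the last step, 1432 rose and then fell, 1017 fell at both and 515 fell and then rose. With no call between these steps, limma gave 3286 that rose at both and 460 that fell at both, and quantile normalization gave 1587 that fell at both. Course counts were not recomputed with single libraries left out. A further 808 (181 with limma) fell and 566 rose from stage 3 to 5 with no other call. Under independent calls 1044.7 genes would rise at both, 1134.3 would rise and then fall, 759 would fall at both and 699 would fall and then rise. The steps share no libraries, but both come from 1 model with 1 spread per gene. A gene with a small spread or many counts is then called more often at both steps, so these expected numbers are not a test. Stage 5 against stage 2, a comparison added after the others were seen, gave 352 genes with edgeR, 121 higher and 231 lower.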

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

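The settings limma on log2(FPKM + 1), DESeq2, library sizes alone, removal of the length trend and leaving out the 4 libraries numbered 10 were chosen after seeing the data, as were all settings for the courses and the length trend for enriched terms. The others were set before. Of the values for named genes under other settings, 2643 kept direction and call, 146 lost the call and 19 turned direction. For the gene lists 1199 kept both, 78 lost the call, 14 gained it and 53 turned. Of the gene counts 99 stayed within 1.5 times and 25 moved further, and for the courses 34 stayed and 8 moved. Leaving out 1 library gave 14499 to 16408 genes for stage 2 against 1, 0 to 94 for stage 3 against 2, 3397 to 7456 for stage 5 against 3, 14537 to 16747 for stage 5 against 1 and 15774 to 16971 for any stages. For stages 5 and 3 the ends beyond 1.5 times were 3397 (without stage 3 replicate 10) and 3818 (without stage 5 replicate 1). A mean of at least 5 FPKM left 10524 genes to test and gave 7870, 4222, 7966 and 8567 calls for stage 2 against 1, 5 against 3, 5 against 1 and any stages. The stage 3 against 2 count was 184 with a pseudocount of 0.1, 145 with quantile normalization, 467 with limma, 682 with DESeq2, 88 without the libraries numbered 10, 1 with the length trend removed and 0 with only the 2 stages fitted; the cause was not tested. Enriched GO terms from stage 3 to 5 went from 229 to 137 among higher genes with the length trend removed, and from 104 to 28 among lower genes with a change of at least 1 on the log2 scale, where fewer genes enter. Depth limits the genes with few counts, and 28380 of 35320 gene models had enough counts to test.

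The labels do not say what the replicate numbers mark, and whether libraries with the same number share a batch is open. Of 18 same-numbered pairs of libraries 16 deviated together with a correlation over 0.1. On average, 9 of 12 libraries correlated most with the libraries of their own number at other stages. The pairs numbered 10 had correlations of 0.221 to 0.427, and on the third principal component the 4 libraries numbered 10 lay at -52.3 to -23.9 and the other 8 at 12.8 to 22.6. With the replicate block the counts were 16280 for stage 2 against 1, 0 for stage 3 against 2, 6499 for stage 5 against 3, 16577 for stage 5 against 1 and 17298 for any stages. With it camera called the extracellular matrix list for stage 5 against 3 (adjusted p = 0.0212, 0.0891 without it). It did not call the flagellum list (0.0510) or the oxidative phosphorylation list (0.0593) for stage 3 against 2. Other lists gained a camera call in settings chosen after seeing the data. Without the libraries numbered 10 these were innate immunity (0.0433) and Wnt, TGF-beta and Notch (0.0414) for stage 5 against 3, and the latter (0.0296) for stage 5 against 1. With the length trend removed they were Wnt, TGF-beta and Notch for stage 5 against 3 (0.0290) and 5 against 1 (0.0249) and extracellular matrix for stage 3 against 2 (0.0396), and with limma innate immunity for stage 5 against 3 (0.0435).

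The named genes that turned direction were a collagen type IV alpha-3-binding protein match (Em0009g1200a), a scavenger receptor gene (Em0022g457a), a 6-4 photolyase (Em0011g1003a), a diacylglycerol acyltransferase (Em0004g412a), an XAP5 match (Em0001g2533a) and pumilio 4-like (Em0005g1324a). With a pseudocount of 0.1 the values were 0.51 for Em0009g1200a, 0.0596 for Em0022g457a and 0.24 for Em0011g1003a (stage 2 against 1), 0.43 for Em0009g1200a, 0.18 for Em0004g412a and 0.46 for Em0011g1003a (stage 5 against 1). With limma on log2(FPKM + 1) the values were 0.50 for Em0009g1200a and 0.21 for Em0011g1003a (stage 2 against 1), 0.42 for Em0009g1200a, 0.17 for Em0004g412a and 0.41 for Em0011g1003a (stage 5 against 1). With library sizes alone the values were 0.39 for Em0009g1200a and 0.14 for Em0011g1003a (stage 2 against 1), 0.31 for Em0009g1200a, 0.00979 for Em0004g412a and 0.35 for Em0011g1003a (stage 5 against 1). With quantile normalization the values were -0.0155 for Em0001g2533a (stage 2 against 1), -0.38 for Em0005g1324a and -0.19 for Em0001g2533a (stage 5 against 1). Some turned values were calls in the other direction, with a pseudocount of 0.1 and with limma on log2(FPKM + 1). These were Em0009g1200a for stage 2 against 1 (limma adjusted p = 0.0127 and 0.0117) and 5 against 1 (0.0293 and 0.0274). Em0011g1003a was called higher for stage 5 against 1 (0.0444 and 0.0421). The other turned values were not called. The cause was not tested.

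Lists whose direction against other genes turned were not called by camera in the turned setting, and their medians are given. With a pseudocount of 0.1 they were 1.24 for chloroplast-matched, 1.54 for lysosome and 1.01 for oxidative stress (stage 2 against 1), 0.26 for adhesion and 0.24 for lysosome (stage 5 against 3), 1.57 for lysosome and 1.19 for oxidative stress (stage 5 against 1). With quantile normalization they were -0.11 for chloroplast-matched and 0.33 for lysosome (stage 2 against 1), -0.0252 for extracellular matrix, -0.0832 for lysosome, -0.0409 for oxidative stress, 0.0784 for lipid and 0.00639 for oxidative phosphorylation (stage 3 against 2), 0.24 for lysosome, -0.13 for oxidative stress and -0.13 for chaperone (stage 5 against 3), 0.38 for lysosome and 0.81 for oxidative phosphorylation (stage 5 against 1). With limma on log2(FPKM + 1) they were 1.04 for chloroplast-matched and 1.49 for lysosome (stage 2 against 1), 0.22 for adhesion and 0.23 for lysosome (stage 5 against 3), 1.38 for lysosome and 1.15 for oxidative stress (stage 5 against 1). With the libraries numbered 10 left out they were 0.23 for chloroplast-matched and 0.44 for lysosome (stage 2 against 1), -0.0205 for lysosome, 0.00536 for oxidative stress and -0.0724 for lipid (stage 3 against 2), 0.0961 for lysosome (stage 5 against 3), 0.46 for lysosome (stage 5 against 1). With the replicate block they were 0.40 for lysosome (stage 2 against 1), 0.31 for lysosome (stage 5 against 1). With library sizes alone they were 1.29 for lysosome (stage 2 against 1), -0.13 for lipid (stage 3 against 2), 0.24 for lysosome (stage 5 against 3), 1.09 for chloroplast-matched, 1.33 for lysosome and 1.22 for oxidative phosphorylation (stage 5 against 1). With the length trend removed they were 0.14 for oxidative phosphorylation (stage 2 against 1), 0.0865 for oxidative stress (stage 3 against 2). With 1 library left out in turn the medians ranged over 0.22 to 0.38 for chloroplast-matched (stage 2 against 1), 0.47 to 0.56 for oxidative phosphorylation (stage 2 against 1), 0.0308 to 0.12 for adhesion (stage 3 against 2), 0.0473 to 0.19 for oxidative stress (stage 3 against 2), -0.0342 to 0.14 for lipid (stage 3 against 2), -0.19 to -0.0205 for adhesion (stage 5 against 3), 0.30 to 0.50 for lysosome (stage 5 against 1). The cause was not tested.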

Other observations

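The tests of the length trend on ribosome and adhesion genes were chosen after the result was seen, as were the genes named in this part and the comparisons of neighbouring and transposon-like genes. Genes with iron storage terms changed between stage 1 and stage 2. The term iron ion transport had 26 of 32 genes higher (adjusted p = 1.55e-05). Its most abundant gene, Em0055g9a, which has no informative description, rose from 2363 ± 496 to 7100.0 ± 460.2 CPM (SD, n = 3 per stage). A ferritin-1 match (Em0055g17a), of the protein that stores iron, rose from 71.3 ± 8.53 to 390.1 ± 188 CPM. Another gene with the term, Em0001g2457a, fell from 6227 ± 1041 to 180.0 ± 37.3 CPM (-5.11 ± 0.72, adjusted p = 9.53e-05), while the nearby Em0001g2445a rose from 585 ± 164 to 3222 ± 1323 CPM. Whether reads were split between these nearby genes was not tested, so their single values are uncertain.

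Genes of other terms moved too. From stage 1 to stage 2 the KEGG pathway Linoleic acid metabolism had 20 of 24 genes higher (adjusted p = 6.87e-05) and peptidyl-tyrosine phosphorylation 75 of 109 (2.05e-09). Among hippo signaling genes 23 of 27 were higher at stage 2 than at stage 1 (1.51e-05). From stage 3 to stage 5 the term small-subunit processome, of ribosome assembly, had 34 of 57 genes lower (1.13e-11). A nucleolar protein 56-like gene (Em0013g128a), of the particles that modify ribosomal RNA, fell from 188 ± 3.27 to 95.8 ± 7.74 CPM (-0.97 ± 0.12, 0.00143).

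Adjacent genes called from stage 1 to 2 had the same direction in 64.8% of 9670 pairs, against a mean of 51.9% and a highest value of 53.8% in 1000 random orders. From stage 3 to 5 the share was 68.8% of 1941 pairs (mean 50.1%, highest 54.4%), and 64.8% of 395 pairs at least 5 kb apart (highest 57.2%). Of 519 genes described like transposons, 10.0% were higher at stage 2 than at stage 1 against 36.0% of other described genes (Fisher p = 1.83e-40), and 24.9% against 22.8% were lower (p = 0.287). From stage 3 to 5 they were called less often both ways, 4.05% against 17.2% lower (Fisher's exact p = 1.70e-19) and 5.59% against 10.1% higher (Fisher's exact p = 0.000404), with a median of 0.29 against -0.04. These tests treat genes as independent, although transposon copies can share reads, so their p-values do not measure the spread between libraries. The groups were not matched for expression level, which also affects how often a gene is called.

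Other splits of the same libraries were counted. The 6 libraries of a comparison have 10 splits into 3 and 3, too few for a share under 0.05. The real splits gave 16006 genes for stage 2 against 1 (highest other 0, so 1 split as large), 2 for stage 3 against 2 (highest other 2, so 2 splits), 6449 for stage 5 against 3 (highest other 1, so 1 split) and 16305 for stage 5 against 1 (highest other 0, so 1 split). Of 100 splits of all 12 libraries only the real split, 1 of 100, gave as many as 17184 genes. Other splits that kept the 3 stage 1 libraries together gave 12469 to 16779 genes, and splits that did not gave 0 to 3. The count thus reflects mainly the distance of stage 1 from the rest and says little on differences between the later stages. Since the libraries of a stage may be technical, these splits cannot exclude chance differences between cultures or animals.

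From stage 3 to stage 5 genes of the ribosome term fell and genes of the homophilic adhesion term rose (31 of 52). The fixed adhesion list, which holds mostly integrin-linked kinase matches, had 0 of 12 called. With each library's length trend removed the ribosome median was -0.65, and the adhesion term kept an adjusted p of 2.98e-08. Without stage 3 replicate 10 the medians were -0.71 and 1.44. These values argue against the length trend or that library as the whole cause. A difference between the stages remains as a hypothesis that rests on the stage labels, since the ribosome term had a median of 0.45 from stage 2 to 3 and of -0.41 from stage 2 to 5 (1 of 153 lower).

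In stage 1, 459 genes were at 0 counts in all libraries and above 10 CPM at a later stage, 64 of them above 100 CPM, against 1, 2 and 1 such genes for stages 2, 3 and 5. They include 20 of 350 genes of extracellular space (adjusted p = 7.98e-06). Stage 5 libraries thinned to the effective depth of stage 1 gave 1 such gene, the same number as before thinning. Thinning can only bring genes with few counts at stage 5 to 0, so this does not decide on depth at stage 1. Only 44 genes had 1 to 3 counts, which would go with failed estimates in the deposited counts. A silent gene would also be at 0, so a failed estimate, a true absence at stage 1 and a part played by depth stay open.

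On log2 CPM, stage 3 libraries were closer to stage 1 than stage 2 libraries were, with mean correlations of 0.693 ± 0.0119 and 0.656 ± 0.0204 (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). The gap between the lowest stage 3 and the highest stage 2 library was 0.0045 (0.0059 on log2(FPKM + 1)), 0.0070 with the length trend removed and 0.0148 among genes of at least 10 CPM, which argues against length and against noise of genes with low counts. Axoneme genes had a median change of -0.35 from stage 2 to 3, or -0.22 with the length trend removed, with 9 of 58 above 0 before that removal and none called by edgeR, where an exchange of the labels of stages 2 and 3 predicts a fall. Stage 5 was also closer to stage 2 than to stage 3 (correlation 0.966 against 0.941, 352 against 6449 genes called, and 1 against 106 of 153 ribosome genes lower), as an exchange predicts. A course that moves back at stage 3 would give the same values, so the exchange and the labelled order both stay open.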
